A study of Mus musculus with 13 samples.

How the data were processed

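The data are bulk RNA-seq counts of enamel organs, the dental epithelium that forms enamel, dissected from mandibular incisors of mice at postnatal day 11. Per the labels, 5 libraries came from mice heterozygous for the Tgfbr2 substitution G357W (Het) and 8 from wild-type littermates (WT). Each library was taken as 1 mouse. Per the labels' protocols, total RNA was made into libraries with an unstranded Nextera XT kit, and the pooled libraries were read as 75-base single reads on a NextSeq 500 in 2 runs. Which library went into which run is not given in the sources used here. The submitters' processing notes name STAR 2.5.2a and the genome build GRCm38, and also name DESeq2, edgeR and limma without saying what each was used for. The counting tool and its annotation are not given in the sources used here.

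The authors deposited raw counts for 48733 features in 13 libraries, and these counts were the input of every test. Of those features, 48709 are Ensembl mouse genes and 24 are spike-in and transgene sequences. The latter took at most 0.000177% of a library's counts and stayed out of library sizes and tests. A filtered count table that the authors deposited holds 21223 features with the same counts in 100% of cases. The features it keeps have at least 6 counts in some library, and those it leaves out reach at most 5. It served as an alternative filter. Another deposited table holds a normalized signal per gene, CPM with trimmed-mean (TMM) scaling by the authors per the table's name. Within each library its values equal the counts times 1 constant, with implied factors from 0.919 to 1.08, and it was used for no test. Gene symbols came from the reference table, which named 48349 of the 48709 genes. Gene positions and the codon of the substitution came from GENCODE mouse release M21 on GRCm38.

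The columns of the tables name the genotype and a number pair such as 1-2 or 4-5, but no replicate number from the labels, so columns were assigned to genotypes only. The number before the hyphen takes 3 values (1, 4 and 5) and is called the library prefix here. The sources used here do not say what it stands for. Prefix 1 holds 1 Het and 3 WT libraries, prefix 4 holds 2 and 3, and prefix 5 holds 2 and 2. Library pairs were compared for identity by a chi-square test of their counts, and the lowest value over 78 pairs was 12.4 per gene, so no library was counted as a repeat of another.

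Genes were filtered with filterByExpr at its default count minimum of 10, which left 16328 genes. They were tested between Het and WT with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit with robust estimation, glmQLFTest), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.227. Standard errors (SE) of log2 fold changes were derived from the F statistic. Values per library are log2 CPM (counts scaled by the TMM-adjusted library size) with a prior count of 2, given as mean ± SD. The 36 gene lists, covering pathways, ameloblast stages, technical signatures and other cell types, were fixed in advance, as were the edgeR and camera tests and the rule for named genes. Each list with at least 5 genes tested (35 of 36) was tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way, were alternatives. Mean levels of lists were compared by exact two-sided permutation tests over all 1287 splits of the libraries into 5 and 8, fixed in advance for the lists of other cell types and technical signatures. The test of the ameloblast lists' means, and every test over the 240 splits that keep each prefix's number of Het libraries, were added after the data were seen.

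The genes named are Tgfbr2, 9 enamel genes (Amelx, Ambn, Enam, Mmp20, Klk4, Amtn, Odam, Wdr72 and Slc24a4), the 8 largest changes and the 4 smallest p in each direction among genes past the threshold with a mean log2 CPM of at least 0, and in each list up to 4 members past the threshold or, with none, the 2 of smallest p as values. Symbols of the Gm and Rik forms were counted but not named by this rule. Any other gene named was chosen after its values were seen, and the text says so where it does. The levels of 1 gene named by this rule are not reported here.

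Data were simulated from the real means and library sizes for Het against WT, with 16328 genes. The gene test recovered 29.9% of the 67 genes changed 1.5-fold, 68.7% of the 67 changed 2-fold and 92.4% of the 66 changed 4-fold. It called 134 genes, of which 7 were unchanged. In the list test, a list of 25 genes shifted by 0.25 on the log2 scale was called, and none of 30 unshifted lists was. The simulated genes varied independently, which genes of a real list need not do.

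Alternatives chosen before the data were examined were RLE and upper-quartile factors, other filters on low counts, DESeq2 1.42.0, limma-voom with and without sample weights, no robust estimation, the mean of 4 Y-linked genes as a covariate, 1 surrogate variable (sva 3.50.0), and each library left out in turn. Added after seeing the data were the prefix as a term, alone or with the Y-linked mean, leaving out the libraries of each prefix, the mean of the fibroblast and mesenchyme list as a covariate, and leaving out the library with the highest skeletal muscle markers in each group (Het 1-2 and WT 1-4).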

Results

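Gene expression was measured in enamel organs of mandibular incisors from 5 Het mice and 8 WT littermates at postnatal day 11. The substitution models a form of Loeys-Dietz syndrome, a connective tissue disorder caused by changes in genes of TGF-beta signalling, and the comparison asks how the enamel organ's transcriptome differs between the genotypes. Total counts per library were 20266079 to 26122340 in Het and 18852382 to 26508410 in WT. Ambn, which encodes the enamel matrix protein ameloblastin, took 20.2% ± 3.17 of the counts in Het (SD, n = 5) and 19.6% ± 3.90 in WT (SD, n = 8).

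Tgfbr2, which encodes the type II TGF-beta receptor, was expressed in all libraries of both genotypes. Its counts were 1464, 2062, 2280, 1533 and 1563 in the 5 Het libraries, and 1001, 1772, 1821, 1601, 1073, 1356, 1556 and 1539 in the 8 WT libraries. The level was 6.19 ± 0.19 log2 CPM in Het (SD, n = 5) and 5.97 ± 0.20 in WT (SD, n = 8). The difference of 0.22 ± 0.11 (SE) was not past the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.741). Within prefixes 1, 4 and 5 the difference was 0.04, 0.52 and 0.06. Tgfbr2 (ENSMUSG00000032440) lies on chromosome 9 from 116084293 to 116175360 on the minus strand (GRCm38). Residue 357 of the 567-residue protein of the shorter annotated isoform is the G that G357W replaces, and its codon lies in exon 4 at 116109687 to 116109689. Gene counts do not tell the alleles apart, so they do not test the genotype of a library.

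Of the 213 genes tested within 10 Mb of Tgfbr2, 0 passed the edgeR threshold, against 14 of 16076 elsewhere. So few calls leave this comparison (two-sided Fisher's exact test, p = 1) little room for any other outcome. At an unadjusted p under 0.05 the shares were 5.63% near Tgfbr2 and 6.92% elsewhere (Fisher's exact p = 0.585).

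Of 16328 genes tested, 14 passed the edgeR threshold, 7 higher and 7 lower in Het, each by at least 1.5-fold. The count depended on the tool and filter: it was 74 with DESeq2 (32 higher, 42 lower), 27 with no filter on low counts, 25 with at least 1 CPM in 5 libraries and 25 with limma-voom and sample weights, and each of these held all 14. Genes with an unadjusted p under 0.05 numbered 1127, where 816.4 are due by chance. The Het and WT ranges did not overlap for 13 of the 14 genes. Over all genes tested the ranges were apart for 0.490%, where chance gives 0.155%.

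Among the genes higher in Het, Lpar3 and Slc6a19 rose most. Lpar3 (ENSMUSG00000036832, chromosome 3, 146220963 to 146286186) encodes a receptor for lysophosphatidic acid. It rose 5.73-fold, from -1.14 ± 0.85 log2 CPM in WT (SD, n = 8) to 1.41 ± 0.30 in Het (SD, n = 5), a log2 fold change of 2.52 ± 0.37 (SE, edgeR adjusted p = 0.00759). Slc6a19 (ENSMUSG00000021565, chromosome 13, 73679745 to 73704865), a transporter of neutral amino acids, rose 4.17-fold, from -0.41 ± 0.53 to 1.59 ± 0.30 log2 CPM (edgeR adjusted p = 0.00248). Dio2, the deiodinase that activates thyroid hormone, rose 2.04-fold to 5.28 ± 0.49 log2 CPM from 4.31 ± 0.26 (edgeR adjusted p = 0.0183). The remaining 4 rose between 1.51-fold and 1.88-fold, with edgeR adjusted p from 0.0125 to 0.0378. These were Otos (otospiralin), Fetub (fetuin-B, a secreted inhibitor of proteases), Susd4 (a regulator of complement) and Cib2 (a calcium- and integrin-binding protein), with log2 fold changes of 0.91, 0.88, 0.86 and 0.59. With 1 library left out, Otos was called in 11 of 13 fits, Fetub and Cib2 in 5 and Susd4 in 3. Susd4 also missed the threshold with the Y-linked covariate (edgeR adjusted p = 0.0522).

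Of the genes lower in Het, Crhr1 showed the largest change. Crhr1 (ENSMUSG00000018634, chromosome 11, 104132855 to 104175523) encodes a receptor for corticotropin-releasing hormone. Its counts were 1, 0, 5, 8 and 13 in the Het libraries and 28 to 97 in the WT libraries. The level fell from 1.56 ± 0.46 log2 CPM in WT (SD, n = 8) to -2.06 ± 1.20 in Het (SD, n = 5), a log2 fold change of -3.70 ± 0.48 (SE, edgeR adjusted p = 0.00248). Kcnip2 (ENSMUSG00000025221, chromosome 19, 45791839 to 45816061), a partner of voltage-gated potassium channels, fell from 1.19 ± 0.33 to -0.33 ± 0.16 log2 CPM (log2 fold change -1.64 ± 0.24, edgeR adjusted p = 0.00759). Atp7b, a copper-transporting ATPase, had a log2 fold change of -1.14 ± 0.19 and fell to 2.79 ± 0.15 log2 CPM (edgeR adjusted p = 0.0200). Gpr4 (a proton-sensing receptor), Galns (a lysosomal sulfatase) and Galnt12 (an enzyme that starts mucin-type O-glycosylation) fell as well, with log2 fold changes of -0.76, -0.75 and -0.70 and edgeR adjusted p of 0.0125, 0.0125 and 0.0368. Galnt12 was the 1 gene of the 14 whose ranges overlapped. The last gene lower in Het, Gm27008, lies outside the naming rule and was named after its values were seen (log2 fold change -1.35).

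**Figure D1:**
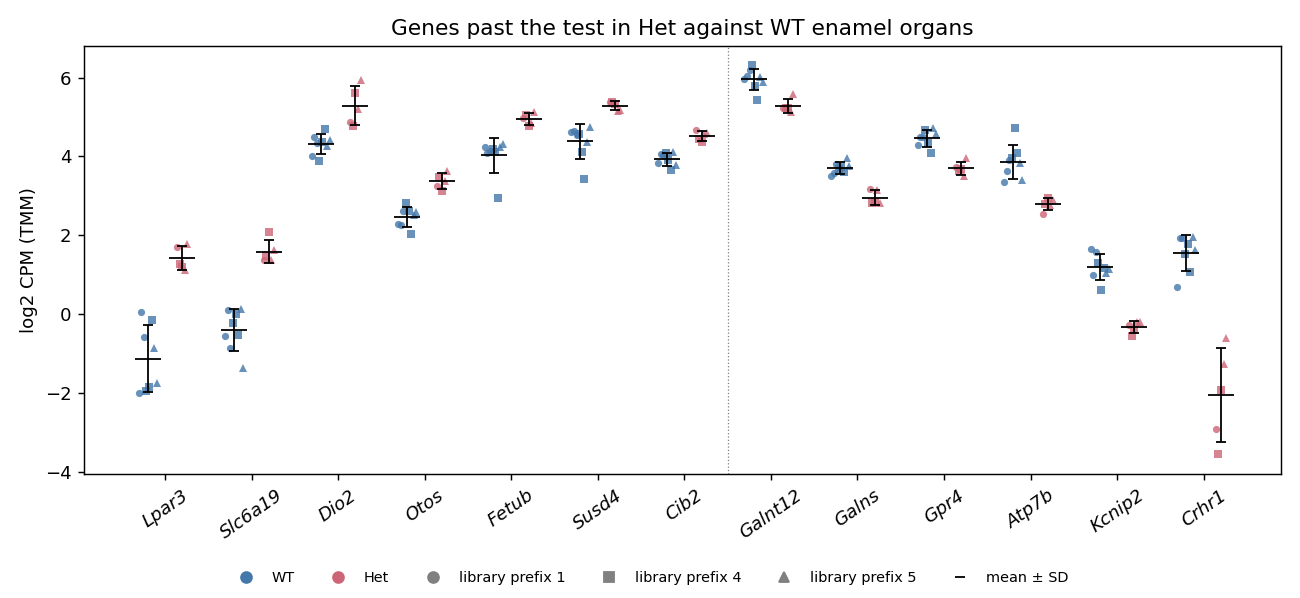
Level of the 13 named genes past the test in each library, as log2 CPM with TMM scaling, for WT (blue, n = 8) and Het (red, n = 5), with marker shape giving the library prefix and black bars the mean ± SD. Lpar3 averaged -1.14 in WT and 1.41 in Het, Crhr1 1.56 and -2.06, and the ranges of the genotypes overlap for Galnt12 only.

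All 13 named genes had the same direction of difference within each of the 3 prefixes. For the 13 of 14 called genes whose ranges do not overlap, direction in any subset of libraries is fixed, so this adds no support. For Crhr1 the differences of mean log2 CPM were -4.43, -4.20 and -2.73 in prefixes 1, 4 and 5, and for Lpar3 they were 2.54, 2.55 and 2.75. With the prefix as a term, an alternative added after seeing the data, edgeR called 30 genes (14 higher, 16 lower), including all 14 of the fit without it. The number of calls depended on single libraries. It was 8 without Het 1-2, 6 without Het 4-2, 7 without Het 5-5, 6 without Het 5-6, 8 without WT 1-1, 9 without WT 1-4 and 22 without WT 5-1, and edgeR called 0 genes without all libraries of prefix 1 (731 at an unadjusted p under 0.05), 1 without those of prefix 4 (AI593442, lower in Het, outside the naming rule and named after its values were seen) and 2 without those of prefix 5 (Crhr1 and Slc6a19). All 14 genes kept their direction in each of these 3 fits, which the lack of overlap fixes for 13 of them. Without prefix 1 the log2 fold changes were about as large (2.71 for Lpar3, 2.09 for Slc6a19, -3.46 for Crhr1, -0.84 for Galns and -1.22 for Atp7b). Because the libraries are unstranded, reads of some genes could come from annotated genes on the other strand. Dio2, Cib2 and Slc6a19 overlap such a gene at 1 end only, and Galns lies wholly within 1. None of these partners was among the genes tested, which does not show how many reads came from them. Gm27008 overlaps 3, of which AI504432 (mean log2 CPM 4.70) and Kcna3 (1.77), both named after their values were seen, were tested and not called. Galns and Galnt12 also hold annotated pseudogenes.

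None of the enamel genes fixed for naming passed the test. Amelx, Ambn and Enam, which encode the main proteins of the secreted enamel matrix, had log2 fold changes of 0.16 ± 0.17, -0.02 ± 0.21 and 0.11 ± 0.18 (SE), and Mmp20, the protease of that matrix, 0.22 ± 0.21. Their edgeR adjusted p lay between 0.860 and 0.992. Genes of the later, maturation stage had lower values in Het without passing the test. Klk4, the maturation-stage protease, had -0.30 ± 0.13 (edgeR adjusted p = 0.666), Amtn (amelotin) -0.45 ± 0.15 (0.502), Odam -0.29 ± 0.18 (0.782), Slc24a4 (a calcium exchanger) -0.23 ± 0.11 (0.730) and Wdr72 -0.13 ± 0.30 (0.953).

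Taken as a list, the maturation-stage ameloblast genes fell in Het with the preset correlation. Of 29 members tested, 24 had a negative and 5 a positive log2 fold change, with a median of -0.23, and none passed over all genes tested (limma camera with Benjamini-Hochberg adjustment over 35 lists, adjusted p = 6.06e-07). The call was lost with limma's other settings, with adjusted p = 0.555 with an estimated correlation and 0.299 with fry. Adjusted over the list alone, 3 members fell, namely Slc39a2 (a zinc transporter, -0.57 ± 0.12), Slc26a1 (a sulfate and anion exchanger, -0.57 ± 0.16) and Cnnm4 (a magnesium transporter outside the naming rule, -0.60 ± 0.18). The mean of the list was 5.50 ± 0.20 log2 CPM in Het (SD, n = 5) and 5.73 ± 0.11 in WT (SD, n = 8; exact two-sided permutation test, p = 0.0179). It was lower in Het in each prefix, by differences of -0.14, -0.38 and -0.12, with an exact permutation p of 0.0333 over splits within prefixes. Both tests of the mean were added after seeing the data, for a list already called by camera on the same libraries. Neither p was adjusted over lists, so they add no independent support to that call. Without Het 4-2, the library with the lowest mean, the difference moved from -0.226 to -0.148 and the exact permutation p was 0.0606. This library also had the highest mean of all 13 for the lists of odontoblast and dental pulp (5.08 log2 CPM) and of dental epithelial stem cell and cervical loop (3.66), and the highest of the Het libraries for osteoblast and bone (5.64). The secretory-stage list was not called, with 21 members tested, 11 positive and 10 negative, a median of 0.07, a mean of -0.02 and a camera adjusted p of 0.879. Its mean level was 7.81 ± 0.11 log2 CPM in Het (SD, n = 5) and 7.72 ± 0.17 in WT (SD, n = 8), a difference of 0.090 (exact permutation p = 0.322) and of 0.09, 0.22 and -0.12 in prefixes 1, 4 and 5. Without Dspp, which encodes a precursor of dentin matrix proteins and was named after its values were seen, the difference was 0.0085 (exact permutation p = 0.910) and the mean log2 fold change -0.0028.

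**Figure D2:**
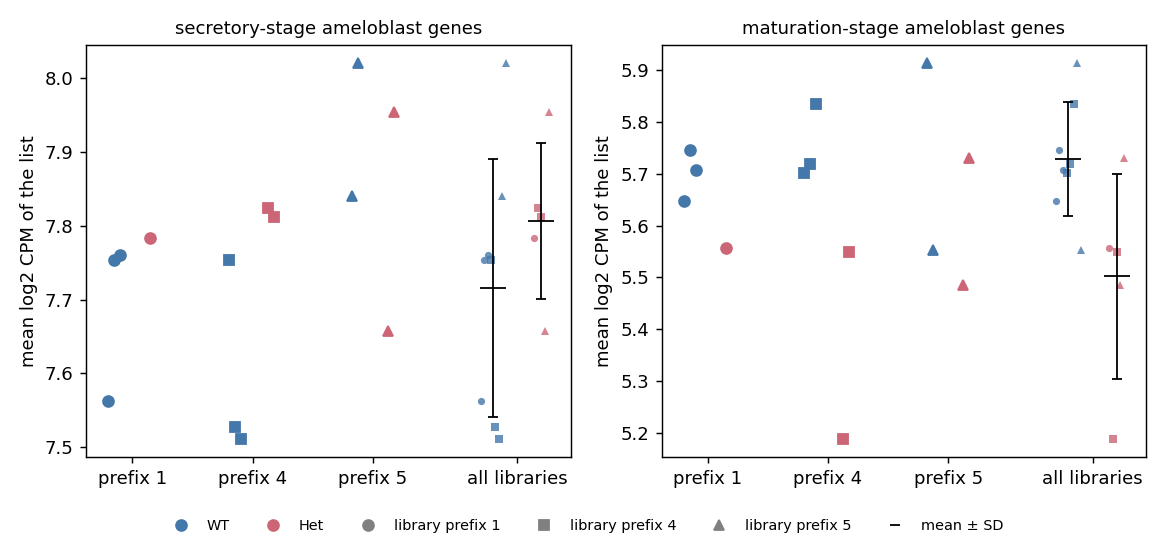
Mean log2 CPM of the secretory-stage list (left) and the maturation-stage list (right) in each library, by library prefix and over all libraries, for WT (blue) and Het (red), with mean ± SD in black for n = 8 WT and n = 5 Het. The maturation-stage mean was 5.50 in Het and 5.73 in WT, and the vertical axes do not start at 0.

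The TGF-beta lists did not pass the test. Of 28 genes known to respond to TGF-beta, 20 had a negative and 8 a positive log2 fold change (median -0.08, limma camera adjusted p = 0.0854, and 0.960 with an estimated correlation). The TGF-beta response list was called as lower in 4 of the 13 fits that left out 1 library, with adjusted p of 0.0193 without Het 4-2, 0.0428 without Het 4-5, 0.0467 without WT 1-1 and 0.0344 without WT 5-1, and had its highest, 0.251, without Het 5-6. The members of smallest p were Pmepa1 (-0.54 ± 0.19, SE) and Snai1 (-0.47 ± 0.17), with edgeR adjusted p of 0.514 and 0.566, and Smad7, the inhibitory SMAD, had -0.40 ± 0.16 (0.635). The list of TGF-beta ligands, receptors and SMADs had a camera adjusted p of 0.668 (24 members, median -0.10), as had the BMP response list (19 members, median -0.06), in which Bmp4 had -0.40 ± 0.14 and Bmpr2 -0.28 ± 0.10.

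No member of any other list passed the edgeR test over all genes. Of list members, only the named ones were followed through the alternatives of the gene test. Among these, Krt18 (adjusted p = 0.00926), Wif1 (0.0427) and Slc39a2 of the maturation-stage list (0.00500) passed with DESeq2. With the mesenchyme covariate, added after seeing the data, Mbp (0.0404) and Slc39a2 (0.0174) passed, and Slc39a2 also with the prefix as a term (0.0460). The osteoclast list was the second list called by limma camera (12 members, 10 negative, median -0.12, adjusted p = 0.0418), with adjusted p = 0.960 with an estimated correlation, and it was called in 7 of the 13 fits that left out 1 library, with the highest adjusted p at 0.327 without Het 5-6. It shares 2 of its 12 members with the maturation-stage list (Car2 and Ctsk, both outside the naming rule), so the 2 calls are not independent. The mean of the osteoclast list over the libraries was 3.32 ± 0.50 log2 CPM in Het (SD, n = 5) and 3.59 ± 0.28 in WT (SD, n = 8; exact permutation p = 0.239), and its leading members Tnfrsf11a and Itgb3 had -0.75 ± 0.27 and -0.42 ± 0.17 (SE). Adjusted over the list alone, single members passed in 4 further lists. In the Wnt pathway list Rnf43 (0.42 ± 0.12) and Wif1 (0.32 ± 0.10) rose and Wnt10b (-0.61 ± 0.19, outside the naming rule) fell. In the keratin list Krt18 rose by 0.91 ± 0.21, in the stratum intermedium and papillary layer list Cd24a rose by 0.51 ± 0.14, and in the pH regulation list Slc26a1 fell.

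The camera adjusted p of the other lists were 0.0893 for mitochondrially encoded genes (called as lower with the prefix as a term at 0.00977, with prefix and the Y-linked mean at 0.0124, with 1 surrogate variable at 0.0206 and without prefix 1 at 0.0356), 0.345 for epithelial keratins and 0.454 for pH regulation and bicarbonate transport. They were 0.668 for iron transport and storage, cell cycle, circadian clock, mitochondrial oxidative phosphorylation, and apoptosis and p53 targets, and 0.748 for calcium handling. The Wnt pathway list had 0.882. The lists of immediate-early and dissociation response, extracellular phosphoproteins and mineralization regulators, Notch, hedgehog and Fgf signals, fibrillar collagens and matrix enzymes, unfolded protein response, endocytosis and lysosome, and basement membrane and cell-matrix adhesion had 0.918, and cell-cell junctions and desmosomes had 0.919. With an estimated correlation limma camera called 0 lists (1 at an unadjusted p under 0.05), and fry also called 0 (1 at an unadjusted p under 0.05).

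Markers of other cell types varied between libraries more than between genotypes. By limma camera the adjusted p was 0.106 for osteoblast and bone, 0.234 for skeletal muscle, 0.668 for fibroblast and mesenchyme and for nerve and Schwann cell, 0.776 for dental epithelial stem cell and cervical loop, and 0.879 for endothelium and pericyte. Some alternatives called these lists. Skeletal muscle was lower with the Y-linked covariate (0.00226), with 1 surrogate variable (0.0206) and without prefix 4 (0.0155), osteoblast and bone with prefix and the Y-linked mean (0.0192) and without prefix 4 (0.0178), and fibroblast and mesenchyme without prefix 4 (0.0176). With 1 surrogate variable fibrillar collagens (0.0206) and endothelium (0.0179) were higher. The adjusted p was 0.918 for the macrophage and other immune cell, oral mucosa, stratum intermedium and papillary layer, erythroid, and odontoblast and dental pulp lists, and the salivary gland list, with 2 genes, was not tested. Over all 1287 splits, mean levels of the 16 lists of other cell types and technical signatures gave 0 exact permutation p under 0.05, with the smallest at 0.0676 for the mitochondrially encoded genes and an adjusted p of 0.891. Over the splits within prefixes, a test added after seeing the data, 1 of the 16 lists was under 0.05, again the mitochondrially encoded genes, with differences of -0.10, -0.16 and -0.15 in prefixes 1, 4 and 5 (exact permutation p = 0.0125, adjusted p = 0.2). Skeletal muscle markers ranged from -0.82 log2 CPM in WT 4-1 to 3.36 in WT 1-4. Without Het 1-2 and WT 1-4, the libraries with the highest muscle markers of their groups, edgeR called 2 genes, Crhr1 (-3.41) and Slc6a19 (2.05). All 14 genes kept their direction, as 13 of them must because their ranges do not overlap.

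Libraries grouped by prefix before they grouped by genotype. The first principal component held 19.2% of the variance, of which prefix explained 78.5% and genotype 9.06%. A Het and a WT library of the same prefix had a mean correlation of 0.299 over 8814 genes centred within genotype, against -0.142 for different prefixes (permutation test, p = 1e-04, the smallest that 10000 permutations can give). The mean of the 4 Y-linked genes was above 0 log2 CPM in 3 Het and 3 WT libraries, among them all 4 libraries of prefix 5. This mean explained 60.4% of the first component, so that component does not tell prefix and Y-linked expression apart.

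**Figure D3:**
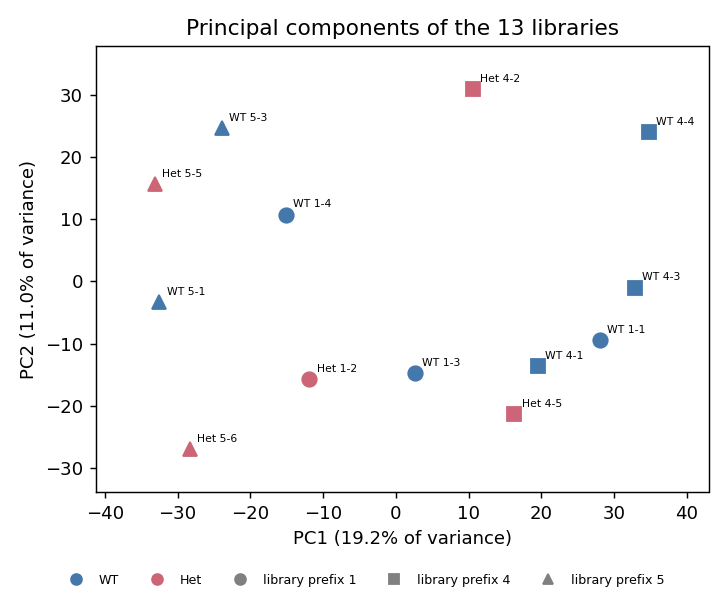
First and second principal components (19.2% and 11.0% of the variance, component scores on both axes) of the 13 libraries, with colour giving the genotype (WT blue, Het red) and marker shape the library prefix. The libraries of prefix 5 lie at the negative end of the first component and those of prefix 4 at the positive side, with both genotypes in each.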

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

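Tests chosen only after the result was seen were both tests of the maturation-stage list (prefixes, share of maturation-stage cells), all tests of the ameloblast lists' mean levels, every test of a mean level over splits within prefixes, both tests of Crhr1, the test of the beta-lactamase sequence and the fits with the prefix as a term; the counts over other splits were written before their results. Other splits of the 13 libraries into 5 and 8, drawn 100 times with the real one included, gave as many as 14 called genes in 1 split, the real one, and the highest other count was 3. For genes higher in Het the real count of 7 was reached in 1 split (highest other 2), and for genes lower in Het also in 1 (highest other 2). These counts come from the same draws, and 1 of 100 is the lowest share such draws can give. Chance is thus unlikely for these counts but not excluded. With the prefix as a term and splits within prefixes, 30 genes or more came in 1 of 100 drawn splits, with the highest other at 2. The genotype stays a hypothesis for these genes, since they were found and tested on the same libraries.

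At least 2 lists were called by limma camera in 89 of the 100 splits, and the highest other count was 19 lists, so chance cannot be excluded for the number of lists called. Which lists were called in a split was not recorded. The splits thus do not test chance for the maturation-stage or the osteoclast list by itself. With the prefix as a term and splits within prefixes, at least the real 3 lists were called in 88 of 100 splits (highest other 20), so chance cannot be excluded there either. Many splits of both kinds call several times the real number, which points to a structure of the samples, not removed by the prefix term, in which genes of a list move together.

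The lower maturation-stage list may have more than 1 source. An uneven spread of genotypes over the prefixes is argued against as the whole cause by a mean difference within prefixes of -0.218 against -0.226 over all libraries. The list mean was lower in Het in each prefix, and with single libraries left out the difference within prefixes lay between -0.278 and -0.157. Whether that difference exceeds chance is less firm. Its exact permutation p was 0.0333 over splits within prefixes, not adjusted over lists and from the libraries that gave the camera call. With single libraries left out, which leaves fewer splits, the p lay between 0.00833 and 0.15 and was under 0.05 in 8 of 13 cases. A stricter criterion, a p under 0.05 also in each of these cases, was weighed after the values were seen and is not met. A lower share of maturation-stage cells in the dissected tissue cannot be told apart from lower expression per cell, because bulk counts do not give the share of cells. Of 21 abundant members, 2 had an interval that excluded the list median (one-sided binomial p = 0.283). This cannot decide, since both explanations allow a common shift and the members are not independent. The secretory-stage list was not called (difference of means 0.090, exact permutation p = 0.322). Chance, for which the counts of called lists above are no test of this list alone, and genotype also stay open.

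For Crhr1, a change of the whole region is argued against by the 16 genes tested within 1 Mb, whose median log2 fold change was -0.090 with 0 called by edgeR (2 at an unadjusted p under 0.05). An uneven spread of Y-linked expression is argued against as the whole cause by the values per library. The Y-linked mean was above 0 log2 CPM in 3 Het and 3 WT libraries, and the Crhr1 ranges of the genotypes did not overlap. The Y-linked covariate could therefore hardly remove the call, so the edgeR adjusted p of 0.00207 with it adds little (range over 18 alternatives 7.18e-15 to 0.0976). A sequence variant at Crhr1 itself was not tested and stays open, as does the genotype at Tgfbr2.

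Single libraries far from the others of their group were found for 10 of 218 groups of values, where chance gives 10.9. Fetub was 2.95 log2 CPM in WT 4-4 against 4.09 to 4.31 in the other WT libraries, and Galnt12 was 5.58 in Het 5-6 against 5.12 to 5.22. Gadd45b was 3.32 in Het 5-5 and Itgb3 3.12 in Het 5-6, against at least 3.63 and at least 3.95 in the other Het libraries. Fth1 was 11.56 in WT 4-3, H2-Aa 4.62 in WT 5-1 and Mylpf 4.66 in WT 1-4, against at most 10.96, 3.93 and 3.19 in the other WT libraries. Among list means, osteoblast and bone was 5.64 in Het 4-2 (others up to 5.17), fibroblast and mesenchyme 6.04 in WT 4-4 (up to 5.47), and oral mucosa and cornified epithelium 2.97 in WT 1-3 (up to 2.22).

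Spike-in and transgene sequences outside the gene counts reached more than 3 counts, the floor that a count of 0 allows, in some libraries. The highest counts in a library were 4 for SIRV1, 14 for SIRV4, 16 for SIRV5, 8 for SIRV6, 7 for SIRV7 and 14 for the beta-lactamase sequence. Its mean count was 7.2 in Het and 3.63 in WT, and CPM did not differ past the threshold (exact permutation test, p = 0.110).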

How the results depend on the processing

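No paired analysis was possible because the columns of the count table carry no replicate number from the labels, so the planned fits with a replicate block and on replicates 1 to 5 without it were not run; the prefix, shared by both genotypes, served as a block added after seeing the data. Alternatives on prefixes, mesenchyme markers and muscle-rich libraries were chosen after seeing the data. The Tgfbr2 level stayed under the threshold in all 18 alternatives of the gene test (differences from 0.030 without prefix 4 to 0.32 without prefix 5) and with each library left out (0.15 to 0.28), and neither the Fisher's exact test near Tgfbr2 with windows of 5 and 20 Mb, which 14 calls leave little room to move, nor the marker levels with RLE factors moved past it. RLE and upper-quartile factors and fits without robust estimation gave 14 genes each, the authors' filter 15, limma-voom 16 (13 shared), the Y-linked covariate 15 (13 shared) and prefix with the Y-linked mean 17 (11 shared). Higher, lower and all genes called were 14, 13 and 27 with no filter, 14, 11 and 25 with at least 1 CPM in 5 libraries, 32, 42 and 74 with DESeq2 (953 genes without an adjusted p), 15, 10 and 25 with limma-voom and sample weights, 11, 10 and 21 with 1 surrogate variable, 14, 16 and 30 with prefix as a term, and 11, 13 and 24 with the mesenchyme covariate, and each of these held all 14 genes. They were 0, 0 and 0 without prefix 1, 0, 1 and 1 without prefix 4 (AI593442, not among the 14, named after its values were seen), and 1, 1 and 2 both without prefix 5 and without the muscle-rich libraries (Crhr1 and Slc6a19 each time). Fewer libraries remain in these fits.

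Without prefix 1, edgeR had 731 genes at an unadjusted p under 0.05 (807.5 by chance), and all 14 genes had the same direction, as they had without prefix 4, without prefix 5 and without the muscle-rich libraries. For the 13 genes whose ranges do not overlap, this direction was fixed in advance. With 1 library left out, called genes ranged from 6 to 22, higher ones from 2 to 10 and lower ones from 3 to 12; Crhr1, Slc6a19, Kcnip2 and Lpar3 were called in all 13 such fits, Otos, Gpr4 and Galns in 11, Dio2 in 10, Atp7b in 8, Cib2 and Fetub in 5, Galnt12 in 4 and Susd4 in 3. Lists called were 2 with RLE factors, with the stricter filter and with sample weights, 3 with the Y-linked covariate, with prefix and without prefix 1, 6 with 1 surrogate variable, 0 with an estimated correlation and 0 with fry, 4 with prefix and the Y-linked mean, 4 without prefix 4, 1 without prefix 5, 1 with the mesenchyme covariate, 1 without the muscle-rich libraries, and 1 to 5 with 1 library left out. Lists gained with 1 library left out were skeletal muscle without Het 1-2 (0.00374), WT 4-1 (0.0171) or WT 4-3 (0.0458), mitochondrially encoded genes without Het 4-5 (0.0428) or WT 1-1 (0.0173), osteoblast and bone without Het 4-2 (0.0102) or WT 1-1 (0.0254), mitochondrial oxidative phosphorylation without Het 4-2 (0.0145, higher), nerve and Schwann cell without Het 5-6 (0.0232, higher) and the TGF-beta response list in 4 fits. The maturation-stage list was called in all 13 such fits and in 12 of 14 alternatives, all but the estimated correlation and fry. All these calls used the preset correlation of 0.01, which only the estimated correlation and fry dropped, so they do not test that choice. Values that changed sign, none past the threshold, were Enam (-0.019 with 1 surrogate variable), Ambn (0.055 without prefix 4, 0.014 without the muscle-rich libraries), Fgf9 (0.087 without prefix 4), Pcp4 (0.078) and Epb42 (-0.074) without prefix 5, and with 1 library left out Ambn (-0.094 to 0.058) and Wdr72 (-0.33 to 0.082). For lists called in neither fit, 124 of 866 comparisons had the other direction. The cause was not tested for any of these. At this depth and number of mice the simulated test recovered 29.9% of 1.5-fold changes, which limits what smaller changes can be called. Its 134 calls, against 14 in the real fit, let a larger unadjusted p pass, so this share can overstate recovery in the real fit.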

Other observations

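With the prefix as a term, an alternative added after seeing the data, 16 genes passed the edgeR threshold that had not passed without it, and the 11 with a gene name are given here after their values were seen. Higher in Het were Tspan6 (log2 fold change 0.72, edgeR adjusted p = 0.0115), Hfe, a regulator of iron uptake (0.60, 0.0231), Gsg1 (0.97, 0.0231), Acpp, an acid phosphatase (0.64, 0.0460), Pde4b, which degrades cyclic AMP (0.61, 0.0463), St7 (0.91, 0.0479) and Fcrl6 (0.87, 0.0479). Lower in Het were Plb1 (-0.76, 0.0231), Steap2, which reduces iron and copper (-0.59, 0.0460), Dennd5b (-0.66, 0.0460) and the zinc transporter Slc39a2 (-0.61, 0.0460). With prefix and the Y-linked mean as terms, edgeR called 17 genes, 11 of them among the 14 called without either term. Most of the 16 genes were thus not called there.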
